A study of Mus musculus with 12 samples.

How the data were processed

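The samples were 12 libraries of ileal RNA from 14-day-old pups, 1 male and 1 female from each of 3 restraint-stressed and 3 control dams. The deposited table of counts holds raw counts of reads for 35275 genes, and the deposited FPKM table holds FPKM values for the same genes and libraries. The authors' table of comparisons holds their log2 fold changes (log2) and, per the file headers, a p-value and an adjusted p-value for each gene. The submitters' processing notes name TopHat, STAR 2.5, HTSeq 0.6.1, DESeq2, edgeR 3.16.5, GRCm38 and mm10. The annotation release is not given in the sources used here. All 240813 nonzero counts were checked against FPKM, and each FPKM equalled the count divided by gene length and library total within 1e-06. Of the gene identifiers 34490 were found in GENCODE M21, 34447 of them at an overlapping place on the same chromosome. Genes were kept apart by identifier, since 52 symbols belong to more than 1 identifier. Library totals ran from 16423523 to 22975526 counts, and no library was a copy of another.

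Comparisons were run in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, genes kept by filterByExpr with its default settings, 16102 genes). 1 fit of the 4 groups, with 8 residual degrees of freedom, gave stressed against control males, stressed against control females, the difference between these changes, and males against females. For the effect over both sexes the counts of littermates were summed, so that the dam was the replicate (3 against 3 dams, 16749 genes). p-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05. Of 49 gene lists fixed beforehand 48 had at least 5 tested members and were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over the lists. A list is said to rise or fall when it passed this test, and its median is over its members. A negative log2 fold change is lower in stressed pups, or in males for the comparison of sexes. CPM values are scaled by TMM.

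The genes to be named were set by a rule: genes past the threshold with a mean of at least 1 CPM over the libraries compared, no clone name and no overlap between the groups, the 12 highest and 12 lowest by log2 fold change. Overlap was not asked of the difference between changes. Where fewer than 5 genes passed, the 10 of smallest unadjusted p were taken and are said not to pass. From each called list the 4 members of smallest unadjusted p were added, and for lists of other cell types the 3 of highest mean CPM. The clones on the Y chromosome and RP23-8J15.1 fall outside the rule and are named because those counts of genes are small. Some genes that the rule takes are not reported here. Genes named for the libraries that stood apart were picked after their values were seen. Groups, comparisons, gene lists and most alternatives were chosen before the data were examined. These alternatives were median-ratio size factors, DESeq2 1.42.0 (Wald test), limma-voom, no filter, a mean of at least 1 CPM, limma on log2(FPKM + 1) and on log2(FPKM + 0.1), the 6 libraries of 1 sex alone, the dam number as a block, 12 pups with sex as a covariate, the dam as a random block, each library left out in turn, camera with an estimated correlation, and fry. Chosen after the data were seen were a correction of each library for its trend with gene length (loess, span 0.5, genes of at least 1 CPM), the same with a block, the fit without both pups of control dam 3, and the fit without the 3 male libraries richest in Yam1 reads. The last leaves 1 stressed male, which the fit assumes to vary like the other groups.

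By the labels the number marks a litter, so littermates pair in the comparison of sexes and in the difference between changes. The numbers do not pair stressed with control dams. The correlation of deviations across genes did not bear out the pairs of littermates, which therefore rest on the labels. It ran from -0.362 to 0.545 between littermates and from -0.329 to 0.306 between stressed and control pups of the same number. The own littermate was the best match only in stressed dam 3 and control dam 3. The tests were tested on simulated data in which 200 of the 16102 genes were changed, 100 by 2-fold and 100 by 4-fold. edgeR recovered 37 and 82 of these in males, 41 and 87 in females, 10 and 57 in the difference, 61 and 95 over dams and 62 and 95 between the sexes. Camera called 1 of 40 unchanged lists. The simulated genes varied independently of each other, so this cannot show how often camera calls unchanged lists whose genes are correlated. In the data the estimated correlation was 0.64 for the mitochondrially encoded and 0.57 for the interferon-stimulated list. With 3 against 3 samples an exact test cannot go below 0.1, and there are 10 splits.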

Results

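The ileum, the last part of the small intestine, was taken from mouse pups on postnatal day 14 and its total RNA was sequenced. The pups came from 6 dams of the C57BL/6 strain. In pregnancy 3 dams had been held in a tube for 2 h a day from gestational day 7 to day 19, a restraint stress, and the other 3 had been left in their home cages. From each dam 1 male and 1 female pup were used, which gave 4 groups of 3 libraries: control males, stressed males, control females and stressed females. The word stressed refers here to the dam. The question of the design is whether stress of the pregnant dam changes gene expression in the ileum of its offspring, and pups of both sexes were taken. The 6 male libraries held between 16423523 and 20075567 counted reads and the 6 female libraries between 20730243 and 22975526, so that every male library was smaller than every female library.

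The sex recorded for each pup matched its sex-linked genes. The Y-linked genes Uty, Kdm5d (histone demethylase family members), Ddx3y (an RNA helicase) and Eif2s3y (a translation initiation factor) lay between 28.2 and 82.2 CPM (counts normalised for library size) in every male and did not pass 0.236 CPM in any female. Xist, the RNA that silences 1 of the X chromosomes in females, lay between 405 and 584 CPM in females and between 0.841 and 2.48 CPM in males.

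Some libraries stood apart from the rest in genes that were chosen after their values were seen. Both pups of control dam 3 held high levels of genes of the upper small intestine. Fabp1, the liver-type fatty acid binding protein of duodenal and jejunal enterocytes, reached 1404 CPM in control male 3 and 168 CPM in control female 3, against 0.151 to 0.638 CPM in the other 10 libraries. Gata4, a transcription factor of the upper small intestine, reached 135 and 51.0 CPM against 0.329 to 4.06 CPM, and Lct, the lactase gene, 5240.1 and 2318 CPM against 157 to 511 CPM. Slc6a14, an amino acid transporter, ran the other way, with 0.13 and 6.37 CPM against 58.5 to 108 CPM. Not all of the genes looked at moved in both pups. Onecut2 stood at 19.4 CPM in control male 3 but at 0.609 CPM in control female 3, against 0.198 to 1.52 CPM. Fabp6 stood at 0.716 and 61 CPM against 29.9 to 607.7 CPM, and Slc10a2 at 0.195 and 1.97 CPM against 1.67 to 6.43 CPM. Genes of the exocrine pancreas were high in the same pups: Ctrb1, a chymotrypsinogen, reached 17.4 and 12.2 CPM against 0.054 to 0.651 CPM, and Clps, colipase, 44.2 and 33.8 CPM against 6.1 to 20.3 CPM. A second set of libraries was rich in reads of Yam1, a noncoding RNA gene on chromosome 17. Stressed male 1, stressed male 3 and control male 1 gave it 1.39%, 4.13% and 1.00% of their reads, against 0.171% to 0.5% in the other libraries. Control male 3 was the highest of these others. In another gene, Gm26917, the 3 libraries stood at 21.3, 52.4 and 25.4 CPM and control male 3 at 20.6 CPM, against 4.86 to 8.68 CPM elsewhere. Stressed male 1 and stressed male 3 also gave 2.18% and 1.16% of their reads to mitochondrially encoded genes, against 3.01% to 4.59% elsewhere. Single control males also differed in cell type lists. In control male 1 the median deviation was -2.03 for Paneth cell, -1.34 for goblet cell, -1.52 for macrophage and -0.83 for cell cycle genes, and 0.72 for smooth muscle and 0.60 for enteric neuron genes. In control male 2 it was -0.65 for smooth muscle, -0.68 for enteric neuron and -0.44 for fibroblast matrix genes.

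**Figure D1:**
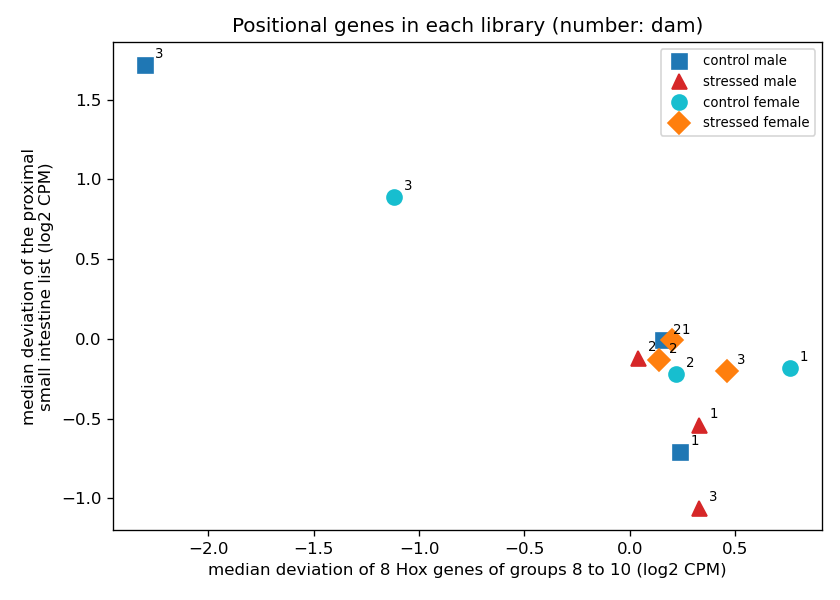
Each point is 1 library: the x axis is the median deviation of 8 Hox genes of groups 8 to 10 from the mean of all libraries, the y axis that of the proximal small intestine genes, both in log2 CPM, with the dam's number beside the point. Both pups of control dam 3 lie at the upper left, at -2.30 and 1.72 for the male and -1.12 and 0.89 for the female, away from the other libraries, whose y values run from -1.06 to -0.01.

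**Figure D2:**
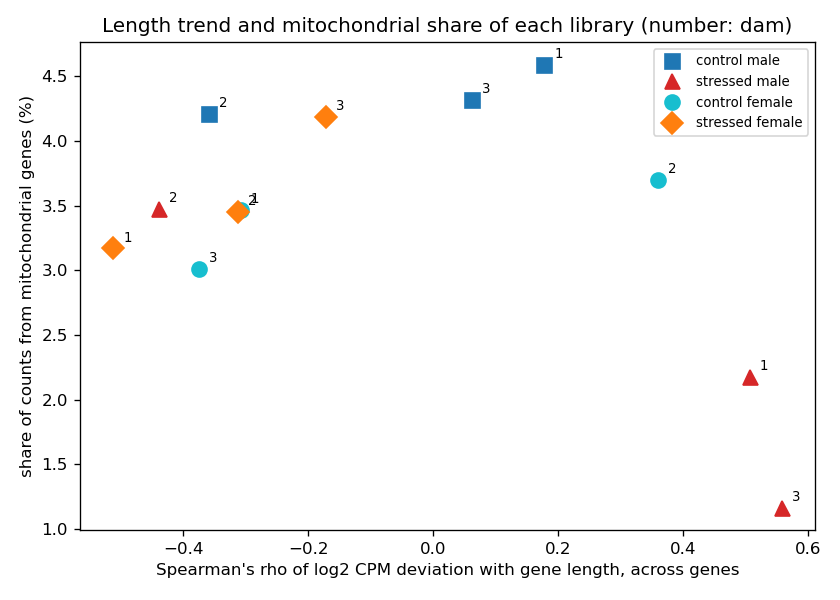
Each point is 1 library: the x axis is the Spearman correlation of its deviation in log2 CPM with gene length, the y axis the percentage of its reads on mitochondrially encoded genes. Stressed male 1 (0.507, 2.18%) and stressed male 3 (0.558, 1.16%) lie at the lower right, and the other libraries run from 3.01% to 4.59%.

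In male pups the clearest difference between offspring of stressed and control dams was in the genes of the mitochondrial genome, which encode subunits of the respiratory chain and of ATP synthase. All 12 measured members were lower in stressed males, with a median log2 fold change of -0.95. mt-Nd3 (chromosome MT, 9459 to 9806, ENSMUSG00000064360), a subunit of respiratory complex I, stood at 18.1 ± 4.40 CPM in stressed males and 33.7 ± 3.04 CPM in control males (SD, n = 3 each). Its log2 fold change was -0.90 ± 0.21 (SE). mt-Nd5, another subunit of complex I, stood at 3490 ± 779 CPM against 6178 ± 1775 CPM, and mt-Nd4 at 1467 ± 724 CPM against 3066 ± 598 CPM. As a list these genes fell (camera with a preset correlation, adjusted p = 4.89e-15), but the adjusted p = 0.708 with an estimated correlation. Adjusted over the list alone 12 of the 12 members passed the threshold, and adjusted over all genes tested 0 did. The list moved together with the libraries named above for their low mitochondrial share: its median deviation was -0.57 in stressed male 1 and -1.60 in stressed male 3, and 0.10 in stressed male 2, against 0.28 to 0.57 in control males. The nuclear genes of oxidative phosphorylation, with 32 of 32 members lower and a median of -0.28, also fell (adjusted p = 3.39e-07 by camera; adjusted p = 0.805 with an estimated correlation), a call lost without control male 3 (adjusted p = 0.0841).

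Several lists that describe the absorptive epithelium and its defence were lower in stressed males as well. Genes of lipid absorption, which take up, re-esterify and export dietary fat, fell with 21 of 23 members below 0 and a median of -0.54 (camera, adjusted p = 4.88e-07; adjusted p = 0.805 with an estimated correlation). Creb3l3, a transcription factor of lipid metabolism genes, stood at 246 ± 22.4 CPM in stressed males against 446 ± 195 CPM in control males, and Fabp2, the intestinal fatty acid binding protein, at 152 ± 91.5 CPM against 837 ± 1131 CPM (SD, n = 3 each), with 2141 CPM in control male 3. The median deviation of the lipid absorption list was 1.21 in control male 3, and its call was lost without that library (adjusted p = 0.137 by camera). Genes of fatty acid oxidation under the receptor PPARα fell with a median of -0.21, and markers of the proximal small intestine with 10 of 11 members below 0 and a median of -1.71 (adjusted p = 0.000507 and adjusted p = 0.00542; for both adjusted p = 0.805 with an estimated correlation). Fabp1 in the last of these stood at 0.369 ± 0.248 CPM against 468 ± 810 CPM, a control mean carried by control male 3. Without control male 3 the calls of fatty acid oxidation (adjusted p = 0.293) and of the proximal small intestine (adjusted p = 0.849 by camera) were lost too. Interferon-stimulated genes, the antiviral response, fell with 33 of 39 members below 0 and a median of -0.28, and genes of antigen presentation with 18 of 20 and -0.36 (adjusted p = 5.59e-05 and adjusted p = 0.00105; for both adjusted p = 0.805 with an estimated correlation). Irf7, a transcription factor that drives type I interferon, stood at 102 ± 24.2 CPM against 168 ± 34.6 CPM, all 3 stressed males below all 3 control males. The list as a whole overlapped between the groups. Its median deviations were 0.14, 0.06 and 0.54 in control males 1, 2 and 3, and -0.45, 0.06 and 0.18 in stressed males 1, 2 and 3. Tapbp, which encodes tapasin and loads peptides on MHC class I, stood at 184 ± 13.8 CPM against 239.0 ± 39.0 CPM, and the call of antigen presentation was lost without control male 3 (adjusted p = 0.639 by camera). Markers of enterocytes after weaning had a median of -1.50 in males without passing the list test (adjusted p = 0.0534), although 6 of them passed when adjusted over the list alone. Their median deviation was 2.27 in control male 3 and no higher than 0.07 in the other males.

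Lists of hormone response, blood vessels and lipid synthesis complete the account of the males. Genes induced by glucocorticoids, the stress hormones, fell with 17 of 20 members below 0 and a median of -0.28. Among them was Cebpd, a transcription factor, with a log2 fold change of -0.97 ± 0.35 (SE). The median deviation of this list was 0.47 in control male 3. In control males 1 and 2 it was -0.01 and -0.04, inside the range of stressed males (-0.39, 0.12 and -0.21). Markers of blood and lymph vessel endothelium fell with 14 of 17 members below 0 and a median of -0.32, among them Cldn5, the tight junction claudin of vessels, with -0.59 ± 0.19. Immediate early genes, which answer cell stimulation within minutes, fell with 17 of 20 members below 0 and a median of -0.18, among them Jun, a part of the transcription factor AP-1, with -0.40 ± 0.12. The call of this list was lost without stressed male 1 (adjusted p = 0.287) or control male 2 (adjusted p = 0.156 by camera). The adjusted p = 0.00105, adjusted p = 1.71e-05 and adjusted p = 0.00322 of these lists (camera) each became adjusted p = 0.805 with an estimated correlation. Cholesterol synthesis genes rose, with 22 of 24 members above 0 and a median of 0.40 (camera, adjusted p = 0.000123; adjusted p = 0.805 with an estimated correlation), and lost their call without control male 3 (adjusted p = 0.143). Lss, lanosterol synthase, stood at 40.8 ± 8.89 CPM in stressed males against 24.4 ± 8.01 CPM in control males. Extracellular matrix genes of fibroblasts, with a median of 0.31, B cell markers, with 0.18, and markers of the mesothelium that covers the gut, with 0.85, rose (camera, adjusted p = 0.0138, adjusted p = 0.0137 and adjusted p = 0.0438; for each adjusted p = 0.805 with an estimated correlation). With the dam number as a block the mesothelium list lost its call (adjusted p = 0.0573), although the numbers of stressed and control dams do not pair. Its call was also lost without stressed male 2 (adjusted p = 0.601), control male 1 (adjusted p = 0.651) or control male 2 (adjusted p = 0.132 by camera), and its median deviations were -1.49, -1.30 and 0.55 in control males and 0.39, 0.74 and -1.13 in stressed males. The fibroblast list lost its call with length correction (adjusted p = 0.0609) and without stressed male 2 (adjusted p = 0.283) or control male 2 (adjusted p = 0.515 by camera), the library low in gut wall markers. The B cell markers turned to lower, without passing, when control male 3 was left out (adjusted p = 0.293 by camera), whose median deviation was -1.84. Their call was also lost without stressed male 2 (adjusted p = 0.102) or stressed male 3 (adjusted p = 0.115 by camera). Apart from the mitochondrial genome, none of the lists called in males had a member that passed when adjusted over the list alone or over all genes.

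Tested 1 by 1, 0 of 16102 genes differed between stressed and control males in edgeR, where the smallest adjusted p was 0.753. DESeq2 and limma-voom also gave 0. At an unadjusted p under 0.05 there were 1028 genes in edgeR, 1136 in DESeq2 and 868 in limma-voom, against 805 by chance. This count shows no excess that holds: it was 252 with the 6 male libraries alone, 330 without stressed male 3, 414 without stressed male 1, 2322 without control male 1 and 3388 without stressed male 2. The genes nearest to the threshold, which did not pass it, included Mmp16 (chromosome 4, 17852893 to 18119145, ENSMUSG00000028226), a membrane-bound matrix metalloproteinase. It stood at 17.6 ± 5.95 CPM in stressed males and 7.66 ± 1.23 CPM in control males (SD, n = 3 each), a log2 fold change of 1.20 ± 0.26 (SE). Chka (chromosome 19, 3851773 to 3894369, ENSMUSG00000024843), the choline kinase that starts phosphatidylcholine synthesis, stood at 94.0 ± 16.1 CPM against 158 ± 29.6 CPM, a log2 fold change of -0.75 ± 0.17. Klb, the co-receptor β-Klotho of endocrine fibroblast growth factors, had 1.24 ± 0.31 and Rassf10, a Ras association domain gene, 1.08 ± 0.26. In each of these 4 genes the 3 stressed males lay outside the range of the 3 control males, which chance gives in 10% of genes. Without stressed male 2 the count of genes rose to 1, RP23-8J15.1, a pseudogene copy of mitochondrial sequence in the nuclear genome with edgeR (log2 fold change -2.44 ± 0.24, adjusted p = 0.0147). Of the 14 calls of lists, 13 were kept without stressed male 1, without stressed male 3 or without control male 1, 11 without stressed male 2 or without control male 2, and 7 without control male 3. Without control male 1 the lists called numbered 24. The list of the mitochondrial genome stayed called in each of these. Without both pups of control dam 3, left out after the data were seen, 8 of the 14 were kept. Those of lipid absorption, fatty acid oxidation, antigen presentation, oxidative phosphorylation, B cells and the proximal small intestine were lost, the B cell markers again turned to lower (adjusted p = 0.272 by camera). Without the 3 libraries rich in Yam1 reads, left out after the data were seen, 6 of the 14 were kept, the mitochondrial genome and lipid absorption among them. The interferon-stimulated, glucocorticoid-induced, cholesterol synthesis, endothelial and immediate early genes, oxidative phosphorylation, B cell markers and the proximal small intestine lost their calls, the immediate early genes turned to higher (adjusted p = 0.868 by camera).

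**Figure D3:**
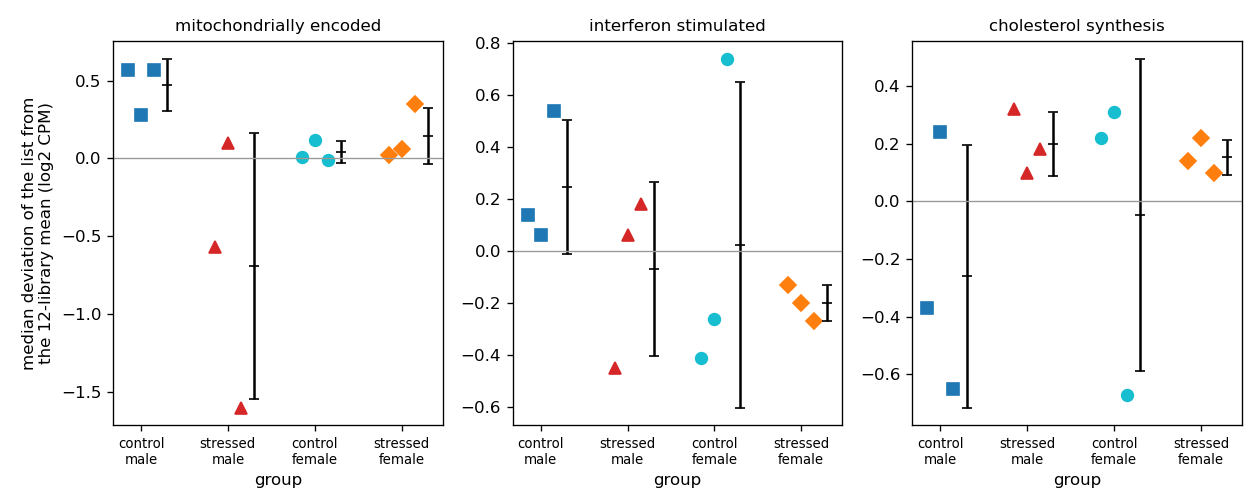
Points are libraries in 4 groups: the y axis is the median deviation of the members of a list from the mean of the 12 libraries, in log2 CPM, and bars are the group mean ± SD. For the mitochondrially encoded genes control males lie from 0.28 to 0.57 and stressed males at -1.60, -0.57 and 0.10; for the interferon-stimulated and cholesterol synthesis genes the highest and the lowest library, at 0.74 and -0.67, is control female 3.

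In female pups the list with the smallest adjusted p by camera was that of interferon-stimulated genes. Of these 37 of 39 were lower in stressed females, with a median log2 fold change of -0.31. Ifit3, an antiviral protein, stood at 16 ± 1.76 CPM in stressed females and 39.3 ± 43.9 CPM in control females (SD, n = 3 each), and Parp14, an ADP-ribosyltransferase of the interferon response, at 95.2 ± 9.63 CPM against 135 ± 51.9 CPM. Cholesterol synthesis genes rose with 20 of 24 members above 0 and a median of 0.12, and B cell markers with 18 of 19 and a median of 0.43. The median deviations of the B cell markers were 0.63, -0.15 and -0.21 in stressed females 1, 2 and 3. In control females 1, 2 and 3 they were 0.01, -0.22 and -0.51. Markers of enterocytes after weaning fell with 14 of 14 members below 0 and a median of -0.46, among them Sis, the sucrase-isomaltase of the brush border, at 10.6 ± 2.85 CPM against 35.6 ± 41.1 CPM. Cell cycle genes fell with 26 of 30 members below 0 and a median of -0.09, and chaperones of the heat shock and unfolded protein responses with 18 of 25 and -0.13. By camera with a preset correlation the interferon-stimulated genes gave adjusted p = 1.62e-05, the B cell markers adjusted p = 0.0493 and the other 4 lists adjusted p = 0.0217. For all 6 the adjusted p = 0.977 with an estimated correlation, and no member passed when adjusted over the list alone or over all genes.

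No gene passed in females: 0 of 16102 in edgeR, with a smallest adjusted p of 1, and 0 in DESeq2 and limma-voom. There were 48 genes at an unadjusted p under 0.05, against 805 by chance, 49 in DESeq2 and 53 in limma-voom. These fits share the estimate of spread with the males. A count below chance is not read here as a result about females. Male replicates differed more, with a chi-square per degree of freedom between 2 libraries of 41.8 to 191, against 8.67 to 75.0 in females. With the 6 female libraries alone the edgeR count was 203 of 15785 genes, still below a share of 0.05. The spread of the males is therefore not the only source of the low count. In the 4-group fit the edgeR count was 152 without control female 1, 30 without stressed female 1 and 31 without stressed female 3. Among those nearest to the threshold, without passing it, Cdc25a (chromosome 9, 109875579 to 109893888, ENSMUSG00000032477), a phosphatase that drives entry into S phase, stood at 73.1 ± 5.05 CPM in stressed and 94.3 ± 11.6 CPM in control females, a log2 fold change of -0.37 ± 0.12 (SE, n = 3 each). Mptx2, a pentraxin of Paneth cells, stood at 9.01 ± 0.919 CPM against 24.1 ± 18.7 CPM. These list calls rested on control female 3, in which the median deviation of the interferon-stimulated genes was 0.74 and that of the cholesterol synthesis genes -0.67. Without it 0 of the 6 calls were kept and 2 were called the other way, the interferon-stimulated genes higher (adjusted p = 0.00179) and the cholesterol synthesis genes lower in stressed females (adjusted p = 0.0411 by camera). Of the 6 calls, 6 were kept without control female 2, 5 without control female 1 or stressed female 2, 4 without stressed female 1 and 3 without stressed female 3. The lists called numbered 12 without control female 1 and 11 without control female 2. Without the 3 male libraries rich in Yam1 reads 4 of the 6 were kept, and cholesterol synthesis (adjusted p = 0.0708) and B cell markers (adjusted p = 0.132 by camera) lost their calls.

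The stress response of males and females was then compared directly, as the change in males minus the change in females. Among the lists called, the mitochondrially encoded genes differed most: all 12 had a lower value, with a median of -1.12. They stood lower in stressed than in control males and had a median of 0.09 in females. Markers of the proximal small intestine had a larger median of -1.49 without passing (adjusted p = 0.202 by camera). mt-Nd3 had -1.24 ± 0.30 (SE, n = 3 per group) and mt-Nd4 -1.13 ± 0.47. The list passed by camera with a preset correlation (adjusted p = 1.40e-13; adjusted p = 0.893 with an estimated correlation), and 1 member, mt-Nd3, passed when adjusted over the list alone. Oxidative phosphorylation (32 of 32 members below 0, median -0.30), lipid absorption (21 of 23, -0.46), fatty acid oxidation under PPARα (18 of 21, -0.23), endothelium (12 of 17, -0.24) and immediate early genes (18 of 20, -0.28) also had lower values in the male response. Cell cycle genes (25 of 30 members above 0, median 0.17) and fibroblast matrix genes (14 of 20, 0.30) had higher values. Cenpf, a kinetochore protein of dividing cells, had 0.86 ± 0.34. By camera the adjusted p values of these lists were 4.30e-06, 0.00135, 0.00904, 0.00434, 0.00434, 0.00904 and 0.0493 in the order named, and for each of them the adjusted p = 0.954 with an estimated correlation, with no member past the threshold when adjusted over the list alone.

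No gene passed the test of the difference: 0 of 16102 in edgeR, with a smallest adjusted p of 0.999, and 0 in DESeq2 and limma-voom. At an unadjusted p under 0.05 there were 346 genes in edgeR, 395 in DESeq2 and 286 in limma-voom, against 805 by chance. Single libraries moved the edgeR count: it was 138 without stressed female 1, 140 without stressed male 3, 141 without control female 2, 166 without stressed male 1, 197 without stressed female 3, 716 without control male 3, 738 without control male 1 and 2138 without stressed male 2. With littermates paired by dam the lists called numbered 13 in place of 8, and all 8 were kept. Without both pups of control dam 3 they numbered 14, with 6 of the 8 kept. Leaving out single libraries gave 14 lists without stressed male 3 or control male 2, 15 without control male 1 and 5 without control female 1, and kept between 3 of the 8, without control male 3, and all 8. The mitochondrially encoded list stayed called throughout, and the lipid absorption list was lost without control male 3 (adjusted p = 0.809) and without control female 1 (adjusted p = 0.102 by camera). The cell cycle list turned to lower, without passing, when control male 1, the library low in cell cycle genes at -0.83, was left out (adjusted p = 0.335 by camera). It also lost its call without stressed male 2 (adjusted p = 0.332) or control female 3 (adjusted p = 0.159 by camera). Without the 3 libraries rich in Yam1 reads 4 of the 8 were kept, and with length correction 7, the fibroblast matrix list being lost (adjusted p = 0.215 by camera).

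**Figure D4:**
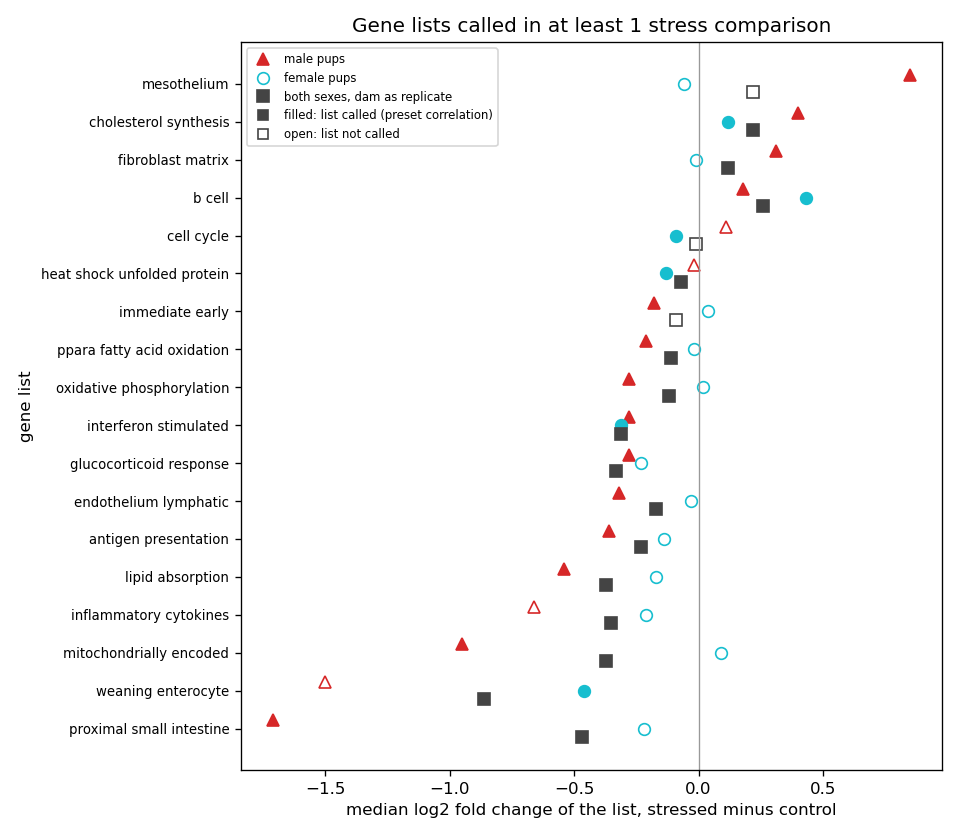
The x axis is the median log2 fold change of a gene list, stressed minus control, for each list called in at least 1 of the 3 stress comparisons, with triangles for males, circles for females and squares for the comparison of dams; filled symbols passed camera with a preset correlation. The mitochondrially encoded genes lie at -0.95 in males, 0.09 in females and -0.37 over dams, and none of the filled symbols stays called with an estimated correlation.

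Over both sexes, with the dam as the replicate and its littermates' counts summed, lists called in males or females were tested again on the same libraries, so this is no separate evidence for them. Mitochondrially encoded genes fell, with 12 of 12 members below 0 and a median log2 fold change of -0.37 (camera, adjusted p = 5.01e-14; adjusted p = 0.735 with an estimated correlation). mt-Nd5 stood at 3454 ± 273 CPM in offspring of stressed dams and 4804 ± 442 CPM in those of control dams (SD, n = 3 dams each), a log2 fold change of -0.48 ± 0.14 (SE), and 4 of the 12 members passed when adjusted over the list alone. Among the libraries summed, stressed males lay at -0.57, 0.10 and -1.60 and control males at 0.57, 0.28 and 0.57, while stressed females lay at 0.02, 0.06 and 0.35 and control females between -0.01 and 0.12. Interferon-stimulated genes fell with 38 of 39 members below 0 and a median of -0.31, and endothelial markers with 15 of 17 and -0.17 (camera, adjusted p = 3.35e-08 and adjusted p = 5.56e-05; for both adjusted p = 0.735 with an estimated correlation). Irf7 stood at 105 ± 9.96 CPM against 147 ± 39.2 CPM. Lipid absorption (22 of 23 below 0, median -0.37), glucocorticoid-induced genes (17 of 20, -0.33), oxidative phosphorylation (32 of 32, -0.12), antigen presentation (19 of 20, -0.23), proximal small intestine (10 of 10, -0.47) and fatty acid oxidation (17 of 21, -0.11) fell too. So did markers of enterocytes after weaning (11 of 13, -0.86), chaperones (19 of 25, -0.07) and inflammatory cytokines (11 of 15, -0.35). Their adjusted p values by camera lay between 5.56e-05 for lipid absorption and 0.0497 for inflammatory cytokines, and for each the adjusted p = 0.735 with an estimated correlation. Cholesterol synthesis genes (22 of 24 above 0, median 0.22), B cell markers (17 of 19, 0.26) and fibroblast matrix genes (17 of 20, 0.12) rose by camera with adjusted p = 0.000257, adjusted p = 0.00455 and adjusted p = 0.0497, and again each had an adjusted p = 0.735 with an estimated correlation. With the dam number as a block the fibroblast matrix list lost its call (adjusted p = 0.0718), although these numbers do not pair. With median-ratio size factors 13 of the 15 calls were kept, and inflammatory cytokines (adjusted p = 0.0654) and fibroblast matrix genes (adjusted p = 0.0507 by camera) were lost. With length correction 12 were kept, and these lists (for both adjusted p = 0.13) and chaperones (adjusted p = 0.132 by camera) were lost. The immediate early (adjusted p = 0.0952) and mesothelium lists (adjusted p = 0.325 by camera), called in males, were not called over dams. In none of the called lists but the mitochondrial one did a member pass when adjusted over the list alone, and 0 members passed over all genes.

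Among single genes 0 of 16749 passed over dams in edgeR (smallest adjusted p 1.00), with 228 at an unadjusted p under 0.05 against 837 by chance. DESeq2 and limma-voom also gave 0, with 229 and 202 at an unadjusted p under 0.05. The edgeR count was 74 without stressed dam 1, 478 without control dam 2, 631 without stressed dam 2 and 1230 without control dam 1. Opn3 (chromosome 1, 175662421 to 175692776, ENSMUSG00000026525), an opsin outside the visual system, was among the nearest without passing, at 2.65 ± 0.0668 CPM against 1.72 ± 0.0418 CPM (SD, n = 3 dams each). Serpinb6b, a serine protease inhibitor, stood at 9.21 ± 1.05 CPM against 13.1 ± 0.915 CPM, and Trac, the constant region of the T cell receptor α chain, at 0.801 ± 0.165 CPM against 1.56 ± 0.314 CPM. The list calls rested largely on control dam 3: without it 7 lists were called, and 2 of the 15 were kept, mitochondrially encoded genes and endothelium. The lists of lipid absorption, oxidative phosphorylation, antigen presentation, proximal small intestine, enterocytes after weaning, cholesterol synthesis and B cells then pointed the other way without passing (camera, adjusted p between 0.530 and 0.957). Without each of the other dams between 12 and 15 of the 15 were kept, and without control dam 1 the lists called numbered 24.

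Of these lists 3 were called in both sexes: interferon-stimulated genes lower, cholesterol synthesis and B cell markers higher, none of them with an estimated correlation. In females none of the 3 kept its call without control female 3. In males without control male 3 the interferon-stimulated genes kept theirs (adjusted p = 0.0206), while cholesterol synthesis (adjusted p = 0.143) and B cell markers (adjusted p = 0.293 by camera) did not. Without both pups of control dam 3 the males kept the calls of interferon-stimulated genes (adjusted p = 0.00526) and of cholesterol synthesis (adjusted p = 0.0223 by camera). Across 16102 genes, which are not independent replicates, the log2 fold changes of males and females had a Pearson r of 0.318, and 48.7% of genes had the same sign. Without both pups of control dam 3, left out after the data were seen, r was -0.192 and 34.1% of genes had the same sign. With all libraries the log2 fold changes followed gene length in opposite directions, with a Spearman correlation of 0.36 in males and -0.211 in females. How much of r comes from this trend was not tested, so r does not show opposite responses to stress.

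Between male and female pups 8 of 16102 genes differed in edgeR, 6 higher in males and 2 lower. Those higher in males were Uty (chromosome Y, 1096861 to 1245759, ENSMUSG00000068457; log2 fold change 8.99 ± 0.22, SE, adjusted p = 9.34e-10), Ddx3y, Kdm5d, Eif2s3y and the clones RP24-498K8.4 and RP24-540G19.3, all on the Y chromosome. The lower ones were Xist (chromosome X, 103460375 to 103483217, ENSMUSG00000086503; -8.27 ± 0.26, adjusted p = 6.49e-09) and Kdm6a (chromosome X, 18162575 to 18279936, ENSMUSG00000037369), a histone H3 demethylase that escapes X inactivation. Kdm6a stood at 33.1 ± 2.99 CPM in males and 56.1 ± 2.33 CPM in females (SD, n = 6 each), a log2 fold change of -0.76 ± 0.08 (SE, adjusted p = 0.0023), with all 6 males below all 6 females. With littermates paired by dam 6 genes were called, 5 higher and 1 lower in males. Lost were RP24-540G19.3 (adjusted p = 0.345) and Kdm6a (adjusted p = 0.0909 in edgeR). For Kdm6a the adjusted p was 0.0535 without the 3 libraries rich in Yam1 reads, and over all its alternatives the values ran from 4.00e-14 with DESeq2 to 0.0909. DESeq2 called 18 genes. In the simulated data of the males DESeq2 called 41 unchanged genes, against 5 in edgeR and 6 in limma-voom. Without stressed male 2 the edgeR count between the sexes rose to 1384, with 954 higher and 430 lower in males. Without the 3 libraries rich in Yam1 reads it was 5.

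The authors' deposited tables of the same comparisons gave 0 genes at an adjusted p under 0.05 in males, in females and over both sexes. Their log2 fold changes and those computed here had Spearman correlations across genes, which are not independent replicates, of 0.983 in males, 0.962 in females and 0.98 over both sexes. Their comparisons of single libraries, which have no replicates, listed 925 genes for stressed against control male 3 and 249 for stressed against control female 3, and between 1 and 171 for the other 4.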

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

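The tests of the region of the intestine, of the change from suckling to weaning, of gene length and of stress in males were chosen after these results were seen; the test of the nuclear copy was chosen before.

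The stress response differed between male and female pups in 8 gene lists by camera with a preset correlation. Adjusted p values were 1.395e-13 for mitochondrially encoded genes, 4.295e-06 for oxidative phosphorylation, 0.00135 for lipid absorption, 0.004339 for endothelium, 0.004339 for immediate early genes, 0.009039 for fatty acid oxidation, 0.009039 for the cell cycle and 0.04931 for fibroblast matrix genes. With an estimated correlation the smallest was 0.893, so no difference between the sexes is shown once the correlation of the genes is estimated. The fibroblast matrix list lost its call after length correction (adjusted p = 0.215).

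Mitochondrially encoded genes were lower in stressed than in control males, which could have come from a bias by gene length between libraries. After correction for length the median was -0.90, against -0.95 before. A bias that acts on these transcripts in another way was not tested. The length trend fitted over genes of at least 1 CPM does not account for their lower level. Reads shared with the nuclear copy on chromosome 1 do not account for it either, since the 5 genes without a copy there had a median of -0.93. Whether stress in males is the cause cannot be told apart, since the difference between the sexes had an adjusted p of 0.893 by camera with an estimated correlation, and the state of the RNA or tissue of stressed male 1 and stressed male 3 was not tested. Without these and control male 1 the list stayed lower, but that fit holds 1 stressed male, stressed male 2. Its median deviation of 0.10 lay below the 0.28 to 0.57 of control males and inside the -0.01 to 0.35 of females. This 1 library cannot decide whether the difference belongs to stressed male 1 and stressed male 3 alone.

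Both pups of control dam 3 held high levels of genes of the proximal small intestine, and a candidate explanation is that a more proximal piece was sampled. The 8 Hox genes of groups 8 to 10 had a median deviation of -1.12 in the higher of the 2 pups, below the lowest of the other libraries, 0.04, which is consistent with that explanation; the pancreatic genes high in the same pups were not part of this test. An earlier change from suckling to weaning predicts high weaning genes and low suckling genes. The median deviation of the weaning list was 0.80 in the female pup and 2.27 in the male pup, against at most 0.07 elsewhere. This part of the prediction held in both pups. That of the suckling list was 0.24 in the female pup, above the median of 0.06 in the other libraries, which speaks against it there. In the male pup it was -0.50, below the lowest other library at -0.40, but the Hox genes were low there too. An earlier change and a more proximal piece cannot be told apart in the male pup. A difference of this litter was not tested.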

How the results depend on the processing

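The fits with length correction, without both pups of control dam 3 and without the 3 male libraries rich in Yam1 reads are tests chosen after the results were seen. With an estimated correlation the lists called were 0 in males, 0 in females, 0 for the difference between the sexes and 0 over dams, and with fry again 0, 0, 0 and 0. For the difference the lists numbered 13 with a block and 14 without both pups of control dam 3. Between the sexes DESeq2 called 18 genes, and 5 were called without the 3 male libraries. Leaving out 1 library gave 0 to 1 genes in males (1 without stressed male 2) and 8 to 1384 between the sexes (1384 without stressed male 2). It gave 12 to 24 lists in males (24 without control male 1), 3 to 12 in females (12 without control female 1, 11 without control female 2, 3 without stressed female 3 or control female 3) and 5 to 15 for the difference (5 without control female 1, 15 without control male 1, 14 without stressed male 3 or control male 2). Leaving out 1 dam, with both of its libraries, gave 7 to 24 lists over dams (7 without control dam 3, 24 without control dam 1).

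The sign of the log2 fold change turned as follows, without control dam 3's pup or pups. Gata4 in males was 0.85 without control male 3 (range over single libraries left out -6.08 to 0.85) and 0.85 without both pups. In females, without control female 3 and without both pups, Ifit3 was 0.19 and 0.18 (range -1.76 to 0.19), Ddx60 0.07 and 0.06 (-1.11 to 0.07), and Trim30a 0.11 and 0.11 (-0.99 to 0.11). Over dams, without control dam 3, Onecut2 was 0.97 (-2.73 to 0.97) and Sis 0.1 (-4.39 to 0.1). Mki67 in the difference was -0.21 without the 3 male libraries. None of these genes passed its test in any of these fits, and the cause was not tested.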

Other observations

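The tests of gene length and of stressed male 2 for the count between the sexes, and the counts over splits, were chosen before their results were seen; the length correction they use was added after the data were seen.

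Over dams, many lists of the gut wall were not called by camera. Tight junction genes had a median log2 fold change of -0.01 (adjusted p = 0.769), Paneth cell genes -0.26 (adjusted p = 0.380), enteroendocrine genes -0.04 (adjusted p = 0.550), enteric neuron genes 0.12 (adjusted p = 0.174), smooth muscle genes 0.03 (adjusted p = 0.247) and T and NK cell genes -0.12 (adjusted p = 0.272). Goblet cell genes had a median of 0.16 and a mean of -0.23, of opposite sign, while the test pointed up (adjusted p = 0.0720). In males the goblet list had a median of 0.29, a mean of -0.11 and again a test pointing up (adjusted p = 0.0534).

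Between the sexes 1384 genes were called by edgeR once stressed male 2 was left out, 1338 of them on autosomes, against 8 with all libraries. Of the 954 higher in males 660 were among the longest 4095 genes, and of the 430 lower 255 were among the shortest 4100. With length correction 132 genes were called, 127 of them among the 1384, which is consistent with a bias by gene length between libraries as a source of most of the calls. A sex difference shared by the males cannot be told apart. Over the autosomal genes called, stressed male 2 had a median signed difference of -0.04 from the female mean, against 0.73, 0.95, 0.42, 0.37 and 0.06 in the other males (median 0.42) and -0.22 to 0.26 in females. Stressed male 2 met the bound set for excluding this source, but the genes were chosen by a fit without it, so its value decides nothing. Control male 2, at 0.06, was in that fit and still lay inside the range of the females, which goes against a difference shared by all males but rests on 1 library.

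For the comparisons of 3 against 3 the 10 splits are too few for a share under 0.05. Where the real count of genes was 0, every split gave as many by definition, so those counts of 10 say nothing. In males 10 of the 10 splits gave as many genes as the real 0 (highest other 2548) and 9 gave as many lists as the real 14 (highest other 24). In females 10 gave as many genes (real 0, highest other 0) and 10 as many lists (real 6, highest other 20). For the difference between the sexes 10 gave as many genes (real 0, highest other 0) and 8 as many lists (real 8, highest other 18), and over dams 10 as many genes (real 0, highest other 0) and 7 as many lists (real 15, highest other 27). Most other splits thus gave at least as many list calls as the real groups. The number of lists called by camera with a preset correlation therefore does not set stress apart from other groupings. The split with 2548 genes sets stressed male 1, stressed male 3 and control male 1 against the other males, which points to a structure of the samples other than stress. These 3 had the highest correlations of deviation with gene length among males, 0.507, 0.558 and 0.178, against -0.439 to 0.063. They are also the libraries rich in Yam1 reads, so these traits cannot be told apart here. For the 8 genes between the sexes 3 of 100 splits, the real one and 99 drawn, gave as many, the real one included. The highest other was 2892. In that split the correlation with gene length ran from -0.172 to 0.558 on 1 side and from -0.512 to -0.308 on the other. It parts the libraries by their trend with gene length, which again points to a structure of the samples. Of the 32 splits that part littermates 1 gave as many, the real one (highest other 0). The 8 genes lie on the sex chromosomes, so a split that mixes the sexes widens their spread within groups. The share of splits therefore says little about chance, and no conclusion is drawn from it.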
